A study of Mus musculus with 2 samples.

How the data were processed

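H3K27me3 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) of hindbrain tissue from mouse embryos at embryonic day 16.5, strain B6NCrl, with tissue of both sexes pooled per the labels. The 2 samples are labelled as biological replicates 1 and 2 of 1 group. Per the labels, the tissue of replicate 2 came from 37 embryos. The number behind replicate 1 was not given in the sources used here. Per the labels, the submitters had files of this experiment under further review at the time of deposit.

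The data used were 4 deposited lists of peaks in the narrowPeak format on the mm10 (GRCm38) assembly, per the text notes deposited with the samples. Replicate 1 and replicate 2 each had a list called on that replicate. A pooled list was called on both replicates together. A list of replicated peaks was derived from the pooled list and both replicate lists, per the same notes. According to these notes, the replicate 1 list and the pooled list drew on 2 further files that the notes do not describe, and the replicate 2 list on only 1 of those. The aligner, the peak caller and its thresholds were not given in the sources used here. For each peak the authors give an integer display score, which was not used. The signal value of each peak in the deposited lists was read as fold enrichment, the authors' ratio of a peak over a control. The notes do not state this for peaks, but they list tracks of fold change over control made from the same source files. The deposited −log10 p-value and −log10 q-value of each peak are also the authors' values, and the lowest −log10 p-value was close to 2 in every list. Peaks were ranked and filtered by these values within a list only. Between lists, medians and shares of these values were compared as descriptions, which depend on the unknown depth of each list. No read counts were among the files used, so sequencing depth is unknown for both replicates.

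Peaks were compared as sets of intervals with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. BEDTools 2.31.1 served for 1 alternative overlap rule, samtools 1.23.1 and pysam 0.24.0 for reading the genome, and matplotlib 3.10.9 for the figures. A peak counted as shared where at least 50% of its own length was covered by the other list. Each share was set against 1000 circular shifts, in which all peaks of a chromosome moved by the same random distance within its sequenced part. Shifting keeps the widths of the peaks and nearly all distances between them. The p-values from shifts were one-sided for the overlap of replicates and two-sided for location. The smallest values they can give are 0.001 and 0.002. Alternatives used 200 shifts.

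Genes were the 21670 protein-coding genes of the GENCODE vM21 annotation on chromosomes 1 to 19 and X, with 54081 transcription start sites (TSSs) of protein-coding transcripts. No list held a peak on chromosome Y, which was left out. A gene carried a peak where at least 1 base within 1 kb of any of its TSSs was covered. A peak was assigned to a promoter if it reached within 1 kb of a TSS, otherwise to an exon, otherwise to an intron, otherwise to the space between genes. The share of a gene body under peaks is the percent of bases from the annotated start to the annotated end of the gene.

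The 15 gene lists were written down before the data were examined. They were the Hox genes of paralog groups 1 to 4 and of groups 5 to 13, transcription factors of forebrain or midbrain, of hindbrain and cerebellum, and of mesoderm and endoderm, secreted signals and antagonists of development, pan-neuronal genes, neural progenitor and glial genes, pluripotency and germline genes, housekeeping genes, olfactory receptors, and markers of endothelium, microglia and macrophages, erythroid cells, and meninges and mesenchyme. The lists other than olfactory receptors held 271 entries, of which 270 were found, Ahsp being the exception. Tbx18 stands in both the mesoderm and the meninges list and is counted in each. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 15 lists. Genes are not replicates, so these tests describe the peak lists and not a population of animals. Hox genes of groups 5 to 13 against groups 1 to 4, and forebrain and midbrain against hindbrain regulators, were compared by Fisher's exact test and, for the covered share of gene bodies, by a two-sided permutation test over genes with 100000 resamples. The p-values of these 4 contrasts were adjusted together. Neighbouring Hox genes share peaks and several gene models overlap, so the genes in these tests are not independent. Intervals for shares are exact 95% binomial (Clopper-Pearson) intervals. For a share of 0, the upper limit given is 3 genes out of the list. Intervals and limits cover counting error only.

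Genes were named by a rule fixed with the lists. It took the extreme genes of each Hox cluster, the 3 members of each list with the most covered bases within 5 kb of a TSS and a peak there in both replicate lists, and up to 2 members with no peak there in any of the 3 lists. It also took up to 3 genes in each of the 10 domains with the most covered bases and always Foxg1, Otx2, Pax6, Atoh1, Ptf1a, En2, Egr2, Gapdh and Actb. Where 5 or fewer members of a list had or lacked a peak, some are also named, a choice made after their values were seen. Domains were made by joining replicated peaks 3 kb or less apart.

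The overlap and list tests were checked on simulated data. With 0%, 30% and 60% of 12430 peaks planted on the other list, the overlap test recovered 0.957%, 30.8% and 60.4%. Planted peaks were exact copies of peaks in the other list, so their recovery checked the code only. Coverage from the interval code differed from a base-by-base count for 0 of 607 peaks. Random gene lists gave p below 0.05 in 2.5% of draws, and lists with 50% of members planted were called in 100%. The simulated lists were all of the same size, larger than the shortest lists tested, and each gene was marked independently. Short lists and neighbouring genes that share peaks were therefore not covered by this check.

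Alternatives covered the overlap rule, stricter thresholds on the authors' values (−log10 q of at least 2, fold of at least 3), and promoter windows of 500 bp and 5 kb. Others were the pooled list, each replicate list alone, the replicate 1 list reduced to the length of the replicate 2 list, and the most upstream TSS only. Further ones were 10000 gene lists matched on the promoter CpG ratio, joining distances of 1 kb and 10 kb, and bases in place of peaks. The promoter CpG ratio is the observed over the expected number of CpGs within 1 kb of the most upstream TSS. Settings added after the data were seen are named as such where their values appear.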

Results

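H3K27me3, a repressive histone mark placed by the Polycomb methyltransferase, was mapped in mouse hindbrain at embryonic day 16.5 in 2 biological replicates of 1 group. Hindbrain at this age comprises the developing cerebellum, pons and medulla. The replicate 1 list held 73065 peaks covering 24.6 Mb and the replicate 2 list 12430 peaks covering 3.90 Mb. The pooled list held 25499 peaks over 12.0 Mb, and the list of replicated peaks held 15139 peaks over 9.43 Mb with a median width of 437 bp. Median fold enrichment, the authors' value, was 3.11 in replicate 1, 3.54 in replicate 2 and 3.70 in the replicated list. Depth is unknown because no read counts were used here. No other tissue or age was analysed here, so the comparisons are between gene groups, between genomic regions and between the 2 replicates.

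Genes that pattern the embryo carried H3K27me3 at their promoters in most cases, while 9.26% of all 21670 protein-coding genes did so in the replicated list. Of 33 transcription factors of mesoderm and endoderm, tissues that do not form the hindbrain, 30 had a replicated peak within 1 kb of a TSS (90.9%, 95% interval 75.7 to 98.1). Of 27 forebrain or midbrain regulators 25 had one (92.6%, 75.7 to 99.1), as did 27 of 32 hindbrain and cerebellar regulators (84.4%, 67.2 to 94.7). Among 22 secreted signals and antagonists of development 19 had one (86.4%, 65.1 to 97.1). Each of these shares exceeded that of the other protein-coding genes, between 9.14% and 9.18%, with adjusted p of 2.55e-27, 1.40e-23, 4.09e-23 and 6.31e-17 in the same order by Fisher's exact test over 15 lists. All 4 lists were also higher in each replicate list alone. Their shares were 100%, 100%, 93.8% and 95.5% in replicate 1 and 87.9%, 88.9%, 62.5% and 77.3% in replicate 2.

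Named members show how much of these loci the mark covered. Lhx6, a regulator of cortical interneurons (chromosome 2, 36081953 to 36105408), had 60.7% of its gene body under replicated peaks, 64.7% under replicate 1 peaks and 25.7% under replicate 2 peaks. Six3, required for the anterior forebrain (chromosome 17, 85613608 to 85629302), had 75.3%, 79.9% and 44.3% in the same order. Nr2e1, an orphan nuclear receptor of forebrain progenitors, had 60.0% under replicated peaks. Foxg1, a telencephalic regulator, had 51.1% covered, and Otx2, a regulator of forebrain and midbrain, had 41.6%. Among mesoderm and endoderm regulators, Tbx1 had 80.5% covered, Pax9 41.3% and Tbx15 16.1% of a longer gene. Among secreted signals, Fgf8 had 88.5% covered, Ihh 86.2% and Wnt10b 67.2%. Replicate 2 peaks covered less of each of these genes, between 7.82% for Tbx15 and 52.7% for Tbx1, with 38.2% for Fgf8 and 29.0% for Ihh. Some members had no replicated peak at a TSS and are named after their values were seen. They were Myf5, Myf6 and Mesp2 in the mesoderm list, Emx1 and Hesx1 in the forebrain list, and Chrd, Dkk1 and Nog in the signal list. All of them except Nog had a replicate 1 peak there. Emx1 had a peak there in both replicate lists, and 33.3% of its gene body lay under replicated peaks.

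The hindbrain regulators held members at both extremes. Fev, a regulator of serotonergic neurons (chromosome 1, 74881509 to 74885419), had 90.0% of its gene body under replicated peaks, 97.9% under replicate 1 peaks and only 20.7% under replicate 2 peaks. Ptf1a, needed for GABAergic neurons of the cerebellum (chromosome 2, 19445663 to 19447501), had 83.0%, 70.9% and 71.6% in the same order. Egr2, a rhombomere regulator, had 60.5% covered, En2 37.7%, Atoh1, needed for cerebellar granule cells, 36.4%, and Pax6 29.1% under replicated peaks. Replicate 2 peaks covered 33.2% of Egr2, 25.5% of En2, 0% of Atoh1 and 8.29% of Pax6. The promoter of Atoh1 had a peak in replicate 1 and none in replicate 2. Meis1 and Meis2, cofactors of Hox proteins, had no peak within 5 kb of a TSS in the replicated list or in either replicate list. Pax3, Rora and Zic2 also lacked a replicated peak within 1 kb of a TSS, a choice of names made after the values were seen, and each had a replicate 1 peak there.

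**Figure D1:**
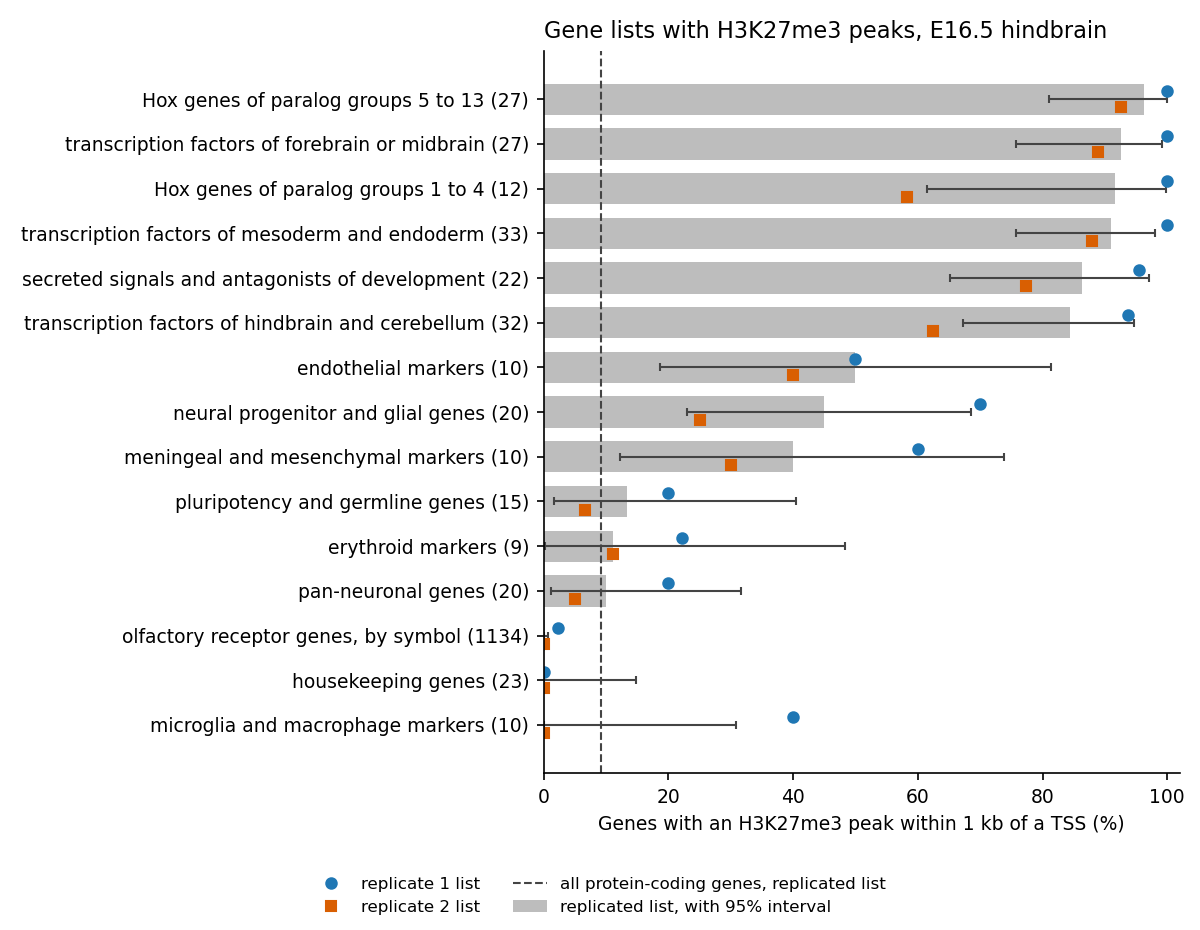
Share of the genes of each fixed list with an H3K27me3 peak within 1 kb of a TSS, in percent on the horizontal axis, with the number of genes in brackets beside each list name, where bars show the replicated list with exact 95% binomial intervals, circles the replicate 1 list, squares the replicate 2 list, and the dashed line the 9.26% of all protein-coding genes. In the replicated list the developmental regulators lie above 84%, in the replicate 2 list they range from 58.3% to 92.6%, and housekeeping genes lie at 0 in every list.

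None of the 23 housekeeping genes of the fixed list, Actb and Gapdh among them, had a replicated peak at a TSS, which allows a share of up to 13%. The difference from other genes missed the threshold in the replicated list (adjusted p = 0.362, Fisher's exact test). With 23 genes against 9.27% of other genes, even a share of 0 could not have passed there. In the longer replicate 1 list 0 members again had a peak, against 18.03% of other genes, and that passed (adjusted p = 0.0335, Fisher's exact test). Of 20 pan-neuronal genes 2 had a replicated peak (10%, interval 1.23 to 31.7, adjusted p = 0.708, Fisher's exact test), namely Rbfox3, which encodes the NeuN protein, and Ina, named after its value was seen. The share was 20% in the replicate 1 list and 5% in the replicate 2 list, against 18.005% and 6.55% of other genes. Replicated peaks covered only 0.838% of the long gene body of Rbfox3 and 0.113% of that of Ina. Ina had no replicate 2 peak within 1 kb of a TSS. Tubb3 and Map2, cytoskeletal genes of neurons, had none within 5 kb of a TSS in any of the 3 lists. Olfactory receptor genes, which are expressed in the nose, had a replicated peak in 2 of 1134 cases (0.176%, interval 0.0214 to 0.636). That was lower than the 9.76% of other genes (adjusted p = 1.33e-44, Fisher's exact test). The share was 2.29% in replicate 1 and 0.0882% in replicate 2, where other genes had 18.9% and 6.90%. Olfactory receptors had a low promoter CpG ratio (median 0.109, against 0.48 over all genes). Lists matched on this ratio had a mean share of 1.74% (central 95% from 1.06 to 2.47). Of 15 pluripotency and germline genes 2 had one, Pou5f1 with 25.7% of its gene body covered and Tdgf1 (13.3%, interval 1.66 to 40.5, adjusted p = 0.690, Fisher's exact test), while Zfp42 and Dppa3 had no peak within 5 kb. That share was 20% in the replicate 1 list and 6.67% in the replicate 2 list.

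Progenitor and glial genes and markers of endothelium and meninges had peaks in 40% to 50% of cases. Of 20 neural progenitor and glial genes 9 had a replicated peak (45.0%, interval 23.1 to 68.5, adjusted p = 6.02e-05, Fisher's exact test). The share was 70% in the replicate 1 list and 25% in the replicate 2 list, above other genes in both. The 9 genes included Olig1 and Olig2, regulators of oligodendrocytes, with 97.55% and 51.1% of the gene body covered, and Gfap, an astrocyte filament, with 30.3%. Replicate 2 peaks covered 57.4%, 22.85% and 11.1% of these genes in the same order. Vim and Fabp7, expressed in radial glia, had none within 5 kb of a TSS. Of 10 endothelial markers 5 had one (50%, interval 18.7 to 81.3, adjusted p = 0.00191, Fisher's exact test), with Sox18 covered over 93.1% of its gene body, Cldn5 over 82.1% and Esam over 11.3%, and with no peak near Cdh5 or Tek. Of 10 meningeal and mesenchymal markers 4 had one (40%, interval 12.2 to 73.8, adjusted p = 0.0146, Fisher's exact test). Among them were Col1a1 with 14.4%, Tbx18 with 13.4% and Aldh1a2 with 1.79% of the gene body covered. Replicate 2 peaks covered 8.54%, 2.65% and 0.219% of these genes in the same order. Col3a1 and Dcn had no peak within 5 kb. With a window of 500 bp the meningeal list no longer passed (20%, adjusted p = 0.240 by the same exact test, between 0.00457 and 0.240 over all alternatives).

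Markers of erythroid cells and of microglia and macrophages could not be told from other genes in the replicated list. Of 9 erythroid genes only Epor, the erythropoietin receptor, had a replicated peak (11.1%, interval 0.281 to 48.2, adjusted p = 0.690, Fisher's exact test), and Gata1 and Hbb-bs had none within 5 kb. The erythroid share was 22.2% in the replicate 1 list and 11.1% in the replicate 2 list. None of 10 microglial and macrophage markers had one, which allows a share of up to 30% (adjusted p = 0.690, Fisher's exact test). With only 10 genes, a share of 0 could not have been called lower. The microglial share was 0 in the replicate 2 list and 40% in the replicate 1 list, above the 17.996% of other genes there without passing the threshold (adjusted p = 0.110, Fisher's exact test). It was 20% against 8.43% of other genes for the best 12430 peaks of replicate 1. Fcgr3, C1qa and C1qc did have replicated peaks farther out, within 5 kb, whereas Csf1r and P2ry12 had none there. With the 5 kb window the microglial share was 40%, above that of other genes (13.3%, adjusted p = 0.0456 by the same exact test, between 0.0456 and 1 over all alternatives). C1qa and C1qc are neighbours that share the same replicated peaks, so the 4 members with a peak stand for 3 loci.

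The 4 Hox clusters had peaks along their length, with the lowest cover by replicated peaks at the paralog group 2 genes Hoxa2 and Hoxb2. Hox genes specify position along the body axis. Paralog groups 1 to 4 were set apart as those expressed in rhombomeres, with the others more caudal. No expression data were used, so which Hox genes were active in this tissue is unknown. Replicated peaks covered 76.9% of the HoxC cluster (chromosome 15, 102921103 to 103036852), 55.2% of HoxD, 52.8% of HoxA and 44.7% of HoxB. Replicate 2 peaks covered 42.2%, 28.8%, 23.4% and 20.8% in the same order, and replicate 1 peaks 80.01%, 65.0%, 61.9% and 55.1%. In HoxA the range ran from Hoxa2, with 0% of its gene body covered (chromosome 6, 52162417 to 52164831), to Hoxa10 with 80.4%. In HoxB it ran from Hoxb2 with 7.999% to Hoxb13 with 92.1%, and in HoxC from Hoxc4 with 51.7% to Hoxc10 with 92.6%. In HoxD it ran from Hoxd9 with 37.5% to Hoxd12 with 93.3%. Replicate 2 peaks covered 0% of Hoxa2 and Hoxb2, and likewise 0% of Hoxa4, Hoxa5 and Hoxb4. They covered 44.8% of Hoxb13, 20.4% of Hoxc4, 61.7% of Hoxc10, 21.3% of Hoxd9 and 62.6% of Hoxd12. The most covered bases within 5 kb of a TSS belonged to Hoxd3, Hoxa3 and Hoxc4 in groups 1 to 4 and to Hoxa10, Hoxb6 and Hoxa7 in groups 5 to 13. This count favours genes with several TSSs, whose windows are wider. The windows held 32763 bases for Hoxd3 and 20002 for Hoxa3 and Hoxc4, against 10001 for Hoxb2. By covered share of the gene body, Hoxd1 (80.5%), Hoxb1 (64.6%) and Hoxd4 (61.4%) led groups 1 to 4.

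**Figure D2:**
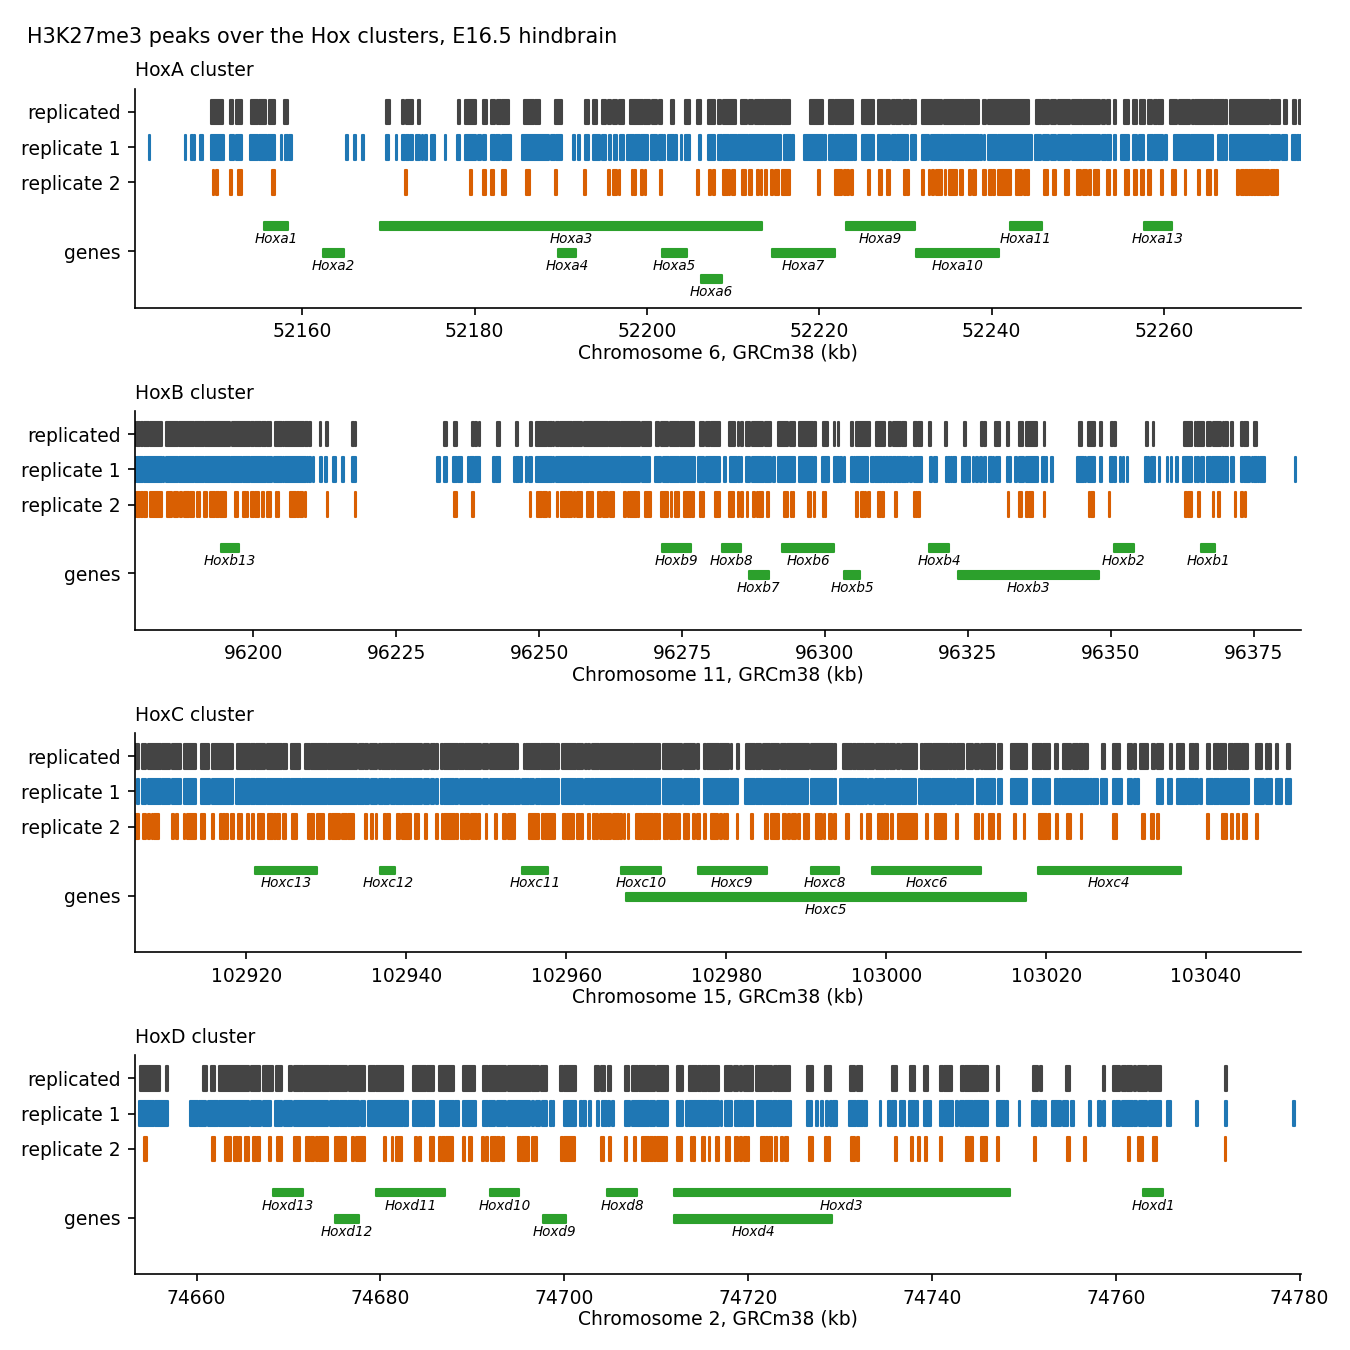
Peaks over the 4 Hox clusters, with position in kb along each chromosome of GRCm38 on the horizontal axis and tracks for the replicated list (grey), the replicate 1 list (blue), the replicate 2 list (orange) and the annotated gene bodies (green). Hoxa2 has 0% of its gene body under replicated peaks and Hoxb2 has 7.999%, against 92.6% for Hoxc10.

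Over all clusters together, gene bodies of paralog groups 5 to 13 were on average covered more than those of groups 1 to 4. The mean covered share was 68.9% ± 20.7 (SD over 27 genes) against 39.6% ± 24.1 (SD over 12 genes), a difference of 29.2 percentage points (permutation test, p = 0.00055, adjusted p = 0.0022 over 4 contrasts). By the same permutation test, the difference was 25.01 points in the replicate 1 list (p = 0.00028). It was 22.2 points in the replicate 2 list (p = 0.00012, permutation test), so it was found in both replicates. The means were 74.7% and 49.7% in replicate 1 and 34.6% and 12.5% in replicate 2. The groups overlapped in HoxD, with Hoxd3 at 47.4%, Hoxd4 at 61.4% and Hoxd1 at 80.5%, against 37.5% for Hoxd9 to 93.3% for Hoxd12. They also overlapped in HoxB, with Hoxb1 at 64.6% against 35.9% for Hoxb5 and 39.7% for Hoxb8. In HoxA, Hoxa5 at 19.7% lay below Hoxa1 at 45.4%, Hoxa3 at 45.2% and Hoxa4 at 23.8%. HoxC, the most covered cluster, supplied only Hoxc4 to groups 1 to 4. The test over genes therefore did not separate paralog group from cluster. At the promoters nearly all Hox genes carried the mark, with 26 of 27 genes in groups 5 to 13 (96.3%, interval 81.0 to 99.9) and 11 of 12 in groups 1 to 4 (91.7%, interval 61.5 to 99.8). Both lists were above other genes (adjusted p = 1.45e-25 and 9.88e-11, Fisher's exact test), and the promoter shares did not differ detectably from each other (4.63 points, p = 0.526). Hoxb5, named after its value was seen, and Hoxa2 were the 2 Hox genes without a replicated peak within 1 kb of a TSS. In the replicate 2 list the promoter shares were 92.6% and 58.3%, and that difference of 34.3 points passed the threshold before adjustment (p = 0.0197, Fisher's exact test).

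**Figure D3:**
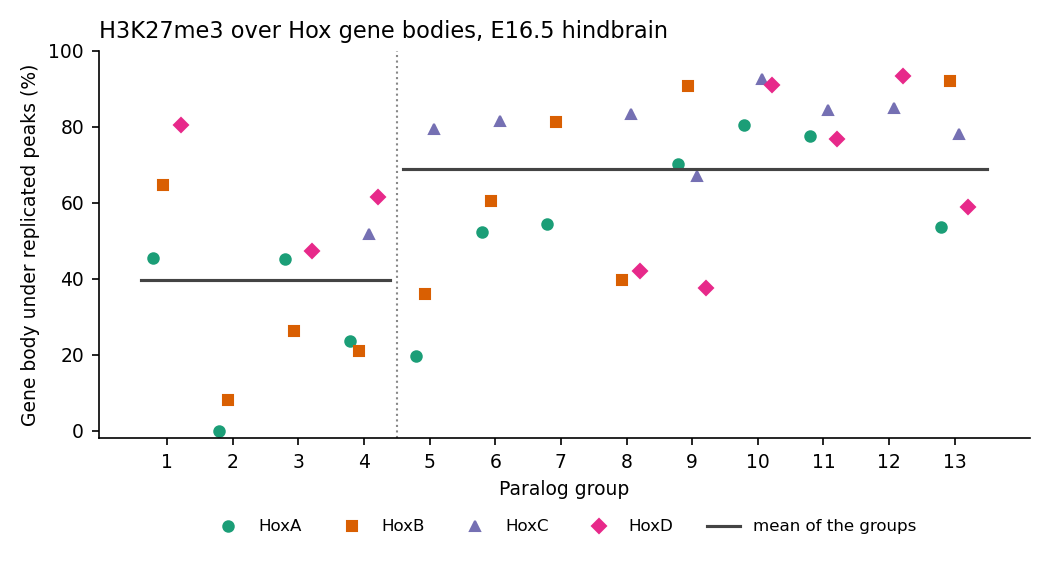
Percent of each Hox gene body under replicated peaks (vertical axis) against paralog group (horizontal axis), with 1 point per gene and a symbol for each cluster. Horizontal lines are the means of groups 1 to 4 (39.6%) and groups 5 to 13 (68.9%), which the dotted line separates.

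Regulators of forebrain and midbrain were compared with those of the hindbrain itself, the regional axis of a hindbrain sample. Their promoters carried replicated peaks at 92.6% and 84.4%, a difference of 8.22 points that Fisher's exact test did not separate from chance (p = 0.437). In the replicate 2 list alone they were 88.9% and 62.5%, and the difference of 26.4 points passed the threshold before adjustment (p = 0.0341, Fisher's exact test). Forebrain and midbrain gene bodies were covered over 45.0% ± 19.6 (SD over 27 genes) and hindbrain gene bodies over 30.9% ± 26.97 (SD over 32 genes). This difference of 14.2 points had p = 0.0278 by permutation and missed the threshold after adjustment (adjusted p = 0.0556). By the same permutation test it was 13.05 points in replicate 1 (p = 0.0417) and 6.33 points in replicate 2 (p = 0.0941).

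The domains with the most covered bases lay over the 4 Hox clusters, single regulators such as Dbx1, Tbx3 and Hand2, the cell cycle inhibitors Cdkn2a and Cdkn2b, and a region at the end of Camkmt. Joining replicated peaks 3 kb or less apart gave 4789 domains with a median width of 1022 bp, of which 341 exceeded 10 kb. These values follow the joining distance, with a median of 599 bp and 154 domains over 10 kb when joined at 1 kb, and 1840 bp and 562 when joined at 10 kb. The domain with the most covered bases spanned the HoxC cluster, including Hoxc4, Hoxc5 and Hoxc6, over 150.2 kb (chromosome 15, 102900286 to 103050466) and had 110.9 kb under replicated peaks, 117.8 kb under replicate 1 peaks and 58.9 kb under replicate 2 peaks. Next came a domain of 110.1 kb around Dbx1, a regulator of ventral interneurons (chromosome 7, 49615222 to 49725354, 70.1 kb covered). The HoxA domain, with Hoxa3, Hoxa10 and the overlapping gene model Gm28308, had 69.0 kb covered. It left out Hoxa1 and Hoxa2 and reached past the other end of the cluster. The HoxB domain, with Hoxb3, Hoxb6 and Hoxb9, had 55.4 kb covered and left out Hoxb1, Hoxb2 and Hoxb13. The HoxD domain, with Hoxd3, Hoxd4 and Hoxd11, had 48.1 kb covered and left out Hoxd1. Then followed Hoxb13 with the end of Ttll6 (39.7 kb), Tbx3, a limb and heart regulator (36.7 kb), a region reaching from the end of Camkmt into the space beyond it (chromosome 17, 85451810 to 85494983, 32.0 kb), Hand2, a heart and limb regulator (31.8 kb), and Cdkn2a with Cdkn2b (chromosome 4, 89266060 to 89314390, 31.7 kb). Each of the 10 domains had between 12.7 and 58.9 kb under replicate 2 peaks.

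Promoters were the location most enriched for peaks. Of the replicated peaks, 24.6% reached within 1 kb of a TSS, against 3.43% ± 0.314 (SD over 1000 shifts). Exons outside promoters took 12.0% (6.69% after shifts), introns 21.6% (32.6%) and the space between genes 41.7% (57.3%). All 4 differences had a permutation p of 0.002, the smallest value the shifts can give. The promoter share was 11.7% in the replicate 1 list and 21.8% in the replicate 2 list, with 3.03% and 3.05% after shifts. With promoters widened to 5 kb the exon share was 4.505%, below the shifted 5.09% (permutation p = 0.1095).

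Chromosome 19 had the highest density of replicated peaks, 12.2 per Mb, and chromosome 3 the lowest, 2.86 per Mb. The X chromosome had 3.63 per Mb, which is 0.616 times the density of the autosomes, and held 4.10% of the replicated peaks (interval 3.79 to 4.43). The ratio was 0.733 in the replicate 2 list, 0.908 in the pooled list and 0.935 when peaks were counted per protein-coding gene, and in the full replicate 1 list it was 1.01. In settings added after the data were seen it was 0.581 for replicated peaks touched by both replicate lists and 0.362 for the best 12430 peaks of replicate 1. By covered bases, X was the lowest chromosome in the replicated list, with 1.34 kb per Mb against 1.71 for chromosome 3. In the replicate 1 list X had 7.43 kb per Mb, within the autosomal range of 5.48 to 16.9. In the replicate 2 list it had 0.812 kb per Mb, within the autosomal range of 0.689 to 3.16.

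Most replicate 2 peaks lay under replicate 1 peaks, while replicate 2 recovered a small part of the longer replicate 1 list. Of the 12430 replicate 2 peaks, 79.7% had at least 50% of their length under replicate 1 peaks, against 1.01% after shifts. Of the 73065 replicate 1 peaks, 5.31% had at least 50% of their length under replicate 2 peaks, against 0.159% after shifts. Both had a one-sided permutation p of 0.001, the smallest value the shifts can give. When each list was reduced to the 12430 peaks with the highest −log10 p, the shares were 61.4% and 20.1%. These shares depend on the overlap rule. Among the 10% of replicate 1 peaks with the highest −log10 p, 59.8% touched a replicate 2 peak. Only 27.5% of them had at least 50% of their length covered. Requiring 50% of the length of both peaks left 2738 peaks of each full list. Requiring 50% of a peak's own length gave 9905 replicate 2 peaks and 3880 replicate 1 peaks. Whether peak width explains these differences was not tested. Replicate 1 had 5.88 times as many peaks, and 37.5% of them had a −log10 q of at least 2, against 2.62% in replicate 2. A −log10 q of 0 was listed for 38.8% of the replicate 2 peaks and for 0 of the replicate 1 peaks. At the level of genes, 1418 had a replicate 2 peak at a TSS and 3902 a replicate 1 peak. Of the 1418, 1378 (97.2%) also had a replicate 1 peak, where independent lists would share 255.

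**Figure D4:**
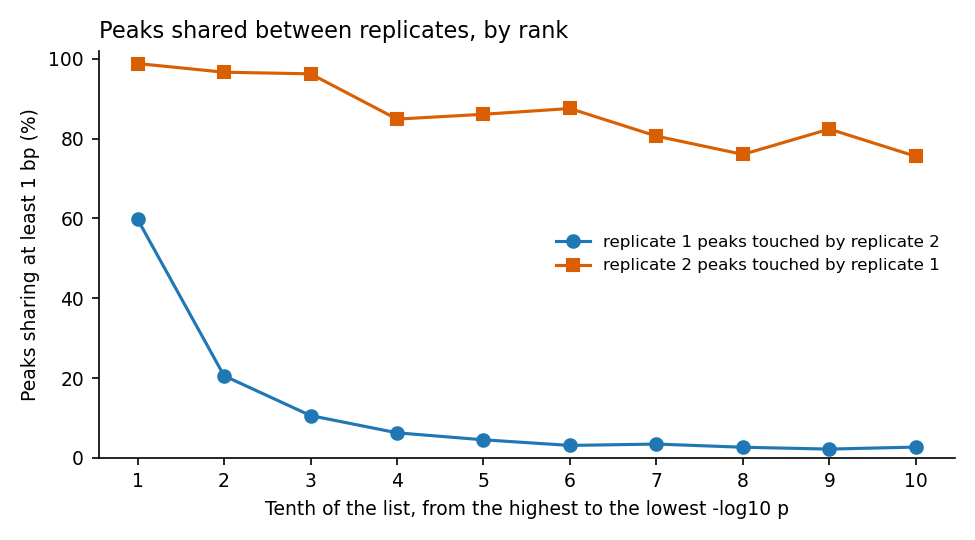
Percent of peaks that share at least 1 bp with the other replicate's list (vertical axis), for successive steps of 10% of a list from the highest to the lowest −log10 p (horizontal axis), with circles for replicate 1 peaks and squares for replicate 2 peaks. The share falls from 59.8% to 2.70% along the replicate 1 list and from 98.8% to 75.5% along the replicate 2 list.

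All 15139 replicated peaks had the coordinates and values of a pooled peak and made up 59.4% of the pooled list. Of these, 94.6% (interval 94.2 to 94.9) had at least 50% of their length under replicate 1 peaks and 32.8% (interval 32.1 to 33.6) under replicate 2 peaks. Counting any shared base, 53.7% touched a replicate 2 peak and 46.3% (interval 45.5 to 47.1) touched none. Membership of the replicated list therefore did not require a peak in the replicate 2 list.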

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

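The replicated list touched by both replicate lists, the replicate 1 list at the length of replicate 2 for chromosomes, and the 50% of either peak rule were chosen as alternatives after the data were seen. Of 283 alternative values for 35 results, 249 were counted as the same, 16 moved, 11 reversed, 4 came to pass the threshold and 3 no longer passed it. For tests, the same meant an unchanged direction and side of the threshold, with contrasts between gene groups judged by p before adjustment. For shares of replicated peaks it meant within the counting interval. For the X ratio it meant within 0.199, the SD of the 2 replicate ratios, which is wider than counting error. Domain counts (6921 and 3837 against 4789) and the number of called lists (8 to 10 against 9) were also counted as the same, although they differed. The higher share of the 9 called lists held under all alternatives run except meninges with the 500 bp window (20%, adjusted p = 0.240, Fisher's exact test), and the Hox gene body difference stayed between 22.2 and 32.2 points (permutation p between 0.00012 and 0.00639). The replicated peaks under replicate 1, replicate 2, both and neither were 96.9%, 53.7%, 52.1% and 1.49% with any shared base, 81.0%, 8.31%, 5.56% and 16.3% with 80% of their length, and 96.1%, 53.3%, 51.3% and 1.87% with 50% of either peak, and these shares moved by construction of the rule. Exons fell to 4.505% when promoters were widened to 5 kb, as promoters then take peaks first. The ratio of X to autosomes was 0.908 in the pooled list, 0.935 per gene, 0.362 for the best 12430 replicate 1 peaks, and from 0.733 to 1.01 with a replicate left out. Microglial markers turned from below to above other genes with the 5 kb window (40%), in the replicate 1 list at the length of replicate 2 (20%), and with a replicate left out (0 to 40%, the higher value from replicate 1). Neuronal genes turned from above to below other genes at −log10 q of at least 2 (5%), with the most upstream TSS (5%), among peaks touched by both replicate lists (5%), against CpG-matched lists (10%), and in the replicate 2 list but not the replicate 1 list (5 to 20% with a replicate left out). Erythroid genes with the 5 kb window (11.1%) and pluripotency genes with the most upstream TSS (6.67%) also fell below other genes. Housekeeping genes stayed at 0 with either replicate left out (0 to 0%), and passed the threshold against the replicate 1 list only, where more of the other genes had a peak (adjusted p = 0.0335, Fisher's exact test, between 0.0335 and 0.544 over all alternatives). The Hox promoter difference was 34.3 points among peaks touched by both replicate lists and 0 to 34.3 with a replicate left out. The forebrain and midbrain against hindbrain difference with a replicate left out was 6.25 to 26.4 points at promoters, the higher value from replicate 2 passing before adjustment (p = 0.0341, Fisher's exact test), and 6.33 to 13.05 points over gene bodies, and the latter was 10.2 points at matched list length (permutation p = 0.119). Apart from the rules named, the cause was not tested. Depth is unknown, so what it limits could not be assessed.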

Other observations

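The tests of gene families, of nearness to replicate 2 peaks, of read number and of repeated sequence in this part were chosen after the results were seen, as were the names of the families, genes and peaks.

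Gene families defined by symbol were compared with other protein-coding genes, over 354 families of at least 8 members with olfactory receptors left out. In the replicated list 21 families were higher and 2 lower by Fisher's exact test after adjustment, and 15 of the 21 and both of the lower ones also passed in each replicate list alone. Of the higher families 4 were Hoxa, Hoxb, Hoxc and Hoxd, whose members all stand in the fixed lists, and several others overlap those lists in part. Wnt genes, secreted signals, had a peak at a TSS in 17 of 19 cases (89.5%, adjusted p = 1.29e-13 by the exact test), with 7 members in the fixed lists. Nkx homeobox genes had one in 12 of 14 cases, with 4 members in the fixed lists, and Lhx homeobox genes in 8 of 8, with 5 members in them. Collagen genes, with 3 members in the fixed lists, had one in 18 of 45 cases (40%, adjusted p = 1.12e-06 by the exact test), with 60.0% in replicate 1 and 20.0% in replicate 2. Among potassium channel genes of the Kcnk family, none of them in a fixed list, 6 of 14 had one, namely Kcnk4, Kcnk6, Kcnk9, Kcnk12, Kcnk13 and Kcnk15 (42.9%, adjusted p = 0.0173 by the exact test). The lower families were vomeronasal receptors, with 0 of 331 genes, and Zfp zinc finger genes, with 8 of 394. The first allows a share of up to 0.906%. The second had 2.03%, with 4.82% in replicate 1 and 0.761% in replicate 2. Vomeronasal receptors had a low promoter CpG ratio (median 0.110), like olfactory receptors, and were not compared with lists matched on it.

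The replicate 1 list was 5.88 times as long as the replicate 2 list, and its 64604 peaks untouched by replicate 2 lay within 10 kb of a replicated peak 10.6 times as often as after shifts (42.3% against 3.98%), a nearness partly built in because the replicated list draws on replicate 1. Measured from replicate 2 peaks, a comparison free of that, 34.4% lay within 10 kb against 3.25% after shifts. This argues against calls spread evenly over the genome as the cause of the whole excess. It does not argue against background that favours the same regions in both replicates. The 37292 peaks more than 10 kb from a replicated peak lay at promoters 1.92 times as often as after shifts, which argues against an even spread of these peaks but not against background that favours open promoters. Fewer reads behind replicate 2 may contribute, since at −log10 p from 4 to 5 its median fold was 1.15 times that of replicate 1 (3.81 against 3.32). The undescribed further files that differ between the replicates and the mixture of cells in each stay open, and no biological explanation was tested because both samples belong to 1 group.

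Developmental regulators were among the 9 gene lists that carried replicated peaks more often than other genes. The promoter CpG ratio alone is argued against, since 9 of the 9 lists lay above the central 95% of 10000 lists matched on it. Matching on this ratio left the number of CpGs free to differ, so CpG density was not tested. An origin in one library is argued against too, since 9 of the 9 lists were called from the replicate 2 list by itself. The mixture of cell types in the tissue stays open, and no biological explanation was tested.

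Among the pooled peaks, the first and the third by −log10 p had a low fold enrichment, 2.37 (chromosome 17, 39843086 to 39846773) and 2.15 (chromosome 17, 39847998 to 39848880), and the annotation places a ribosomal RNA gene at both. The second, in an intron of Cdk8 (chromosome 5, 146261003 to 146261474), had a fold of 4.82. Collapsed copies of a repeated sequence are a candidate explanation for the low fold. That 2 of the 20 highest peaks lay below the median fold of the list (3.29) restates the pattern and says nothing on repeated sequence, so collapsed copies cannot be told apart from other causes. No biological explanation was tested.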
